A study of Streptomyces noursei with 2 samples.

How the data were processed

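The series holds 2 RNA-sequencing libraries of the soil bacterium Streptomyces strain NBRC 14147, a producer of ε-poly-L-lysine, a polymer of lysine units joined through their side-chain amino groups. The organism label reads Streptomyces noursei, while the series title calls the species Streptomyces albulus. Per the labels' protocols, the cells came from a stirred jar fermentor that was fed ammonia water after growth had given way to production, which kept the broth acidic. The growth-phase library was taken at 8 h and the production-phase library at 35 h. Ribosomal RNA was removed with a bead-based kit and strand-specific libraries were prepared, per the labels' protocols.

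Reads were trimmed with Trimmomatic 0.39 and aligned with BWA 0.7.17, per the submitters' processing notes. StringTie 2.1.3b then quantified only the annotated transcripts of assembly ASM385166v1, with a reverse-strand setting, per the file headers. For each of 8383 transcripts the deposited files give TPM, FPKM and the mean per-base coverage, written as attributes of the transcript, per the file headers. TPM is corrected for transcript length and sums to the same total in both libraries, so it carries relative abundance and no absolute amount of RNA per cell. The gene models hold coding lengths, since 97.2% of the lengths are multiples of 3, so no untranslated regions are described. How reads that align to several places were assigned is not given in the sources used here, so values of near-identical copies are uncertain.

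The authors' deposited table compares the libraries. It gives a log2 fold change and a log2 mean abundance per transcript. It also gives a likelihood ratio score and, from it, a p-value and an FDR, all by the authors. The submitters' processing notes name edgeR 3.16.5 for this step. The authors' values tie as whole counts of coverage times length in units of 100 bases, rounded up, would. Among transcripts with under 20000 aligned bases in each library, 136 combinations of a growth and a production count were shared by at least 2 transcripts. In 135 of them the authors' log2 fold change and log2 mean abundance were equal to 9 decimals, and the next best unit of those tried from 50 to 151 bases gave 97.3%. The deposited scores correspond to a single biological coefficient of variation of 0.443 for the 515 transcripts on which it could be solved, with 5th and 95th percentiles of 0.443 and 0.443. With 1 library per phase this value cannot have come from replicates of a phase. The deposited p-values and FDRs are therefore quoted only as the authors' values.

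Gene symbols were taken from the deposited files, which pair 701 of the 8383 transcripts (8.36%) with 582 distinct symbols, and 7682 transcripts carry none. Product descriptions were not used here. Transcripts without a symbol are given by contig, from 1 to 8 in the order of the assembly, and by coordinates on ASM385166v1. The 94 features with an RNA-type identifier include 84 without a symbol.

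For each transcript the ratio log2((production TPM + 1)/(growth TPM + 1)) was computed, with a pseudocount of 1 TPM, which understates differences of low transcripts. A transcript was measured if it reached 10 TPM in a library. It was called higher or lower by the size rule at a log2 ratio of at least 2 or at most -2, a 4-fold difference. With 1 library per phase no difference has a replicate check, no test across samples was possible and no p-value was computed. Depth was expressed as read equivalents, the aligned bases divided by 100. Intervals on a ratio of TPM are exact 95% conditional binomial intervals on these read equivalents and cover counting error only. Reads without molecular identifiers are not independent molecules. The median interval reached 0.0950 to either side on the log2 scale among measured transcripts, and for 94.5% of them it reached less than 0.25. The floor for a transcript listed at 0 is 3 read equivalents.

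Before the data were examined, 32 gene lists were fixed by symbol or product name, covering polymer synthesis, the lysine pathway, translation, respiration, central metabolism, stress responses, development and other functions. Because only symbols could be matched, lists hold the part of each function that carries a symbol. A list's median log2 ratio was set against 10000 random lists of equal size drawn from the measured transcripts and matched on mean expression in 20 bins. A list was said to stand apart below the 1st or above the 99th percentile, as a description of these 2 libraries. Lists with fewer than 3 measured members are given by their values alone. Random lists drew transcripts singly, so neighbours within a list that may be transcribed together count as independent. The pools were not cleared of members of the list or of other lists. The percentile among random lists of transcripts with a symbol was added after seeing the data. That background of 507 measured transcripts includes the 48 measured ribosomal protein transcripts, so for these it is partly a comparison with themselves.

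The genes named were set beforehand by a rule: every measured member of the polymer and lysine lists, the 12 highest and 12 lowest log2 ratios, the 3 largest absolute ratios and the most abundant member of each other list, and the 5 most abundant transcripts of each library. Members of lists that did not stand apart could be left out. Genes named outside this rule are marked as chosen after their values were seen.

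The size rule was tested on simulated data for this comparison of 4400 transcripts. It picked up 0%, 50%, 100% and 100% of 50 transcripts each with true log2 ratios of 1, 2, 3 and 4. Random lists of 12 members passed the outer percentiles in 1 of 100 cases with no shift and in 97 of 100 with a shift of 0.5. The simulated noise was independent between transcripts and narrower than the real spread, with quartiles of -0.18 and 0.67. These shares check the calculation and do not carry over to the real lists. A share near 50% at a true ratio equal to the threshold holds by construction. Alternatives were another pseudocount, another filter, FPKM, centring on the median or a trimmed mean, leaving out the 10 most abundant transcripts, other size thresholds and the authors' fold changes. The files did not name ribosomal and transfer RNA as such, so the planned removal of these classes was run on all 94 RNA-type features, a change made after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.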

Results

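The transcriptome of the poly-lysine producer NBRC 14147 was profiled in 1 library from the growth phase, at 8 h of fermentation, and 1 from the production phase, at 35 h. The growth library held 4.94 Gb of bases aligned to the assembly, of which 4.56 Gb (92.3%) lay on annotated transcripts. The production library held 3.94 Gb and 3.64 Gb (92.4%). These correspond to 45.6 M and 36.4 M read equivalents of 100 bases on transcripts. Coverage was above 0 for 8368 of 8383 transcripts in growth and for 8379 in production, and 3773 and 4226 reached 10 TPM. No phase had a second library, so every difference described here is a difference between these 2 libraries without a replicate check.

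Few RNAs made up much of both libraries. The most abundant was ssrA, the transfer-messenger RNA that releases stalled ribosomes, with 22.9% of TPM in growth and 23.4% in production. It was followed by rnpB, the RNA of ribonuclease P, which trims transfer RNA precursors, with 7.77% and 8.83%. The next 3 were the same in both libraries by rank, a transcript without a symbol on contig 6 at 2568270 to 2568503 (21789 and 25968 TPM), groES, a chaperonin subunit (15654 and 12458 TPM), and a transcript on contig 6 at 4502747 to 4502950 (13507 and 10830 TPM). The 10 most abundant transcripts together held 38.6% and 39.4% of TPM.

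**Figure D1:**
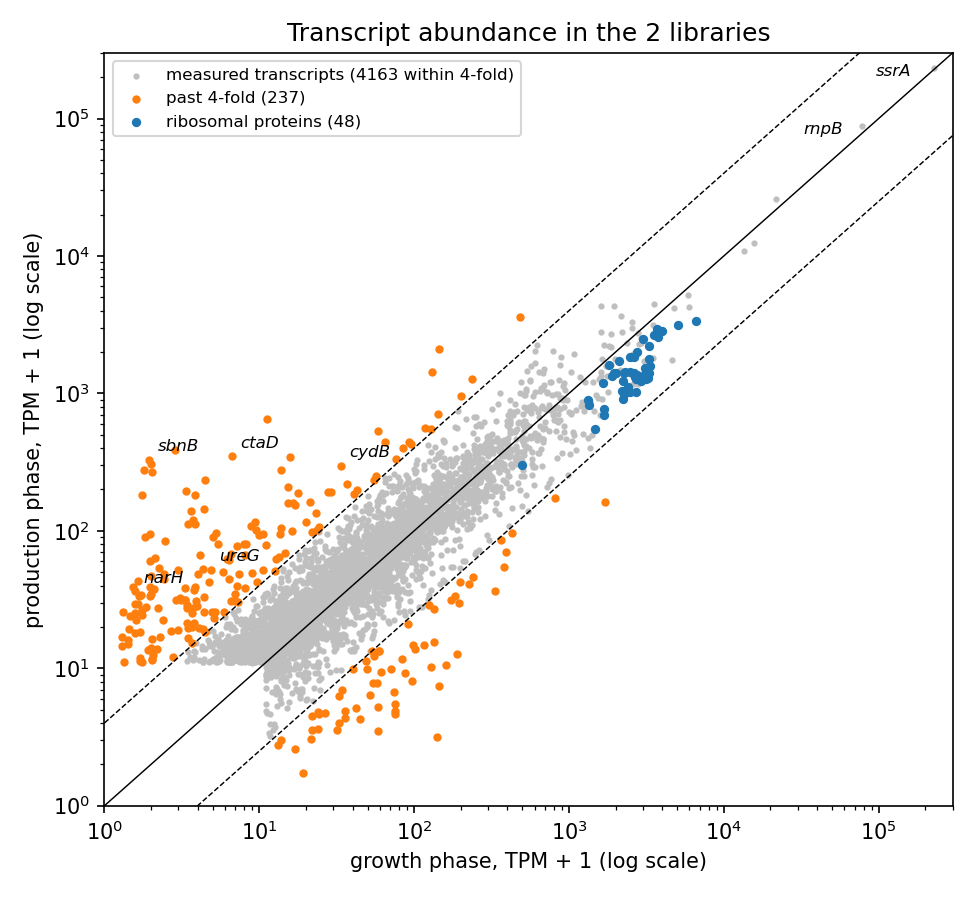
TPM plus 1 of each measured transcript in the growth-phase library (x axis, log scale) and the production-phase library (y axis, log scale), 1 library each. The solid line marks equal values and the dashed lines a 4-fold difference. The 237 transcripts past 4-fold are orange and the 48 measured ribosomal protein transcripts, all below the line of equal values, are blue.

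The comparison of production with growth asks which transcripts differ when the culture makes the polymer. A stretch of 6 transcripts that holds sbnA and sbnB was far more abundant in the production library, as were 2 scarce copies of the oxidase gene ctaD and both measured cytochrome bd genes. Transcripts for ribosomal proteins and nucleotide synthesis were less abundant as groups. Among 4400 measured transcripts, 172 (3.91%) were higher in production by the size rule and 65 (1.48%) were lower. The log2 ratios ran from -5.46 to 7.40. Their median was 0.25, with quartiles of -0.18 and 0.67, so the typical measured transcript had a slightly higher TPM in production. Of the calls, 72.6% were higher. After centring on the median transcript the counts were 149 higher and 97 lower, or 60.6% higher. By the authors' deposited fold changes, whose median was -0.25, they were 140 higher and 142 lower, or 49.6%. Adding only the authors' near-constant offset to the log2 TPM ratios, a setting added after seeing the data, gave 129 and 131. The excess of higher calls therefore depended on the scaling between the libraries. For the lists that stood apart and the lysine list, medians are also given relative to the median of 0.25.

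All 11 measured transcripts with a symbol that passed the size rule were higher in production, and none of the 507 measured transcripts with a symbol was lower by it. They were sbnB, sbnA, 2 copies of ctaD, narH, narJ, ureG, ccrA, cydD, cydB and corA. Of these, narH, narJ, ccrA and corA lie outside the naming rule and are given because the count is small, after their values were seen. The nitrate reductase genes narH, for the iron-sulfur subunit (0.574 and 35.3 TPM, log2 ratio 4.53), and narJ, for its assembly chaperone (0.303 and 15.9 TPM, 3.70), lie next to each other on contig 1 from 280727 to 282951. The gene ccrA, for crotonyl-CoA carboxylase/reductase of the ethylmalonyl-CoA pathway, had a log2 ratio of 3.37 (contig 7, 2074410 to 2075786, 5.57 and 67.0 TPM). The gene corA, for a magnesium transporter, had 2.79 (contig 7, 787703 to 788788, 26.9 and 192 TPM). Another copy of each of ccrA and corA, also chosen after its value was seen, had log2 ratios of -0.07 and 0.53.

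The largest differences lay in a single stretch of contig 6. There, 6 consecutive transcripts on the plus strand, from 603725 to 613695, had log2 ratios between 6.70 and 7.40 and took the 6 highest places of all. Their growth-phase levels were 0.757 to 1.85 TPM and their production-phase levels 181 to 387 TPM. Symbols are given for sbnB (610818 to 611882) and sbnA (611919 to 612902), named after genes that make L-2,3-diaminopropionate for a siderophore in staphylococci. The sbnB transcript had 0.949 TPM in growth and 329 in production, a 347-fold ratio with a counting interval of 278 to 439. The sbnA transcript had 1.85 and 387 TPM, a 209-fold ratio with an interval of 177 to 248. In the authors' deposited table the log2 fold change of sbnB was 7.91 with an FDR of 5.66e-07, and that of sbnA was 7.19 with an FDR of 2.09e-06. Other copies of sbnB and sbnA on contigs 1 and 2 stayed below 10 TPM in both libraries.

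**Figure D2:**
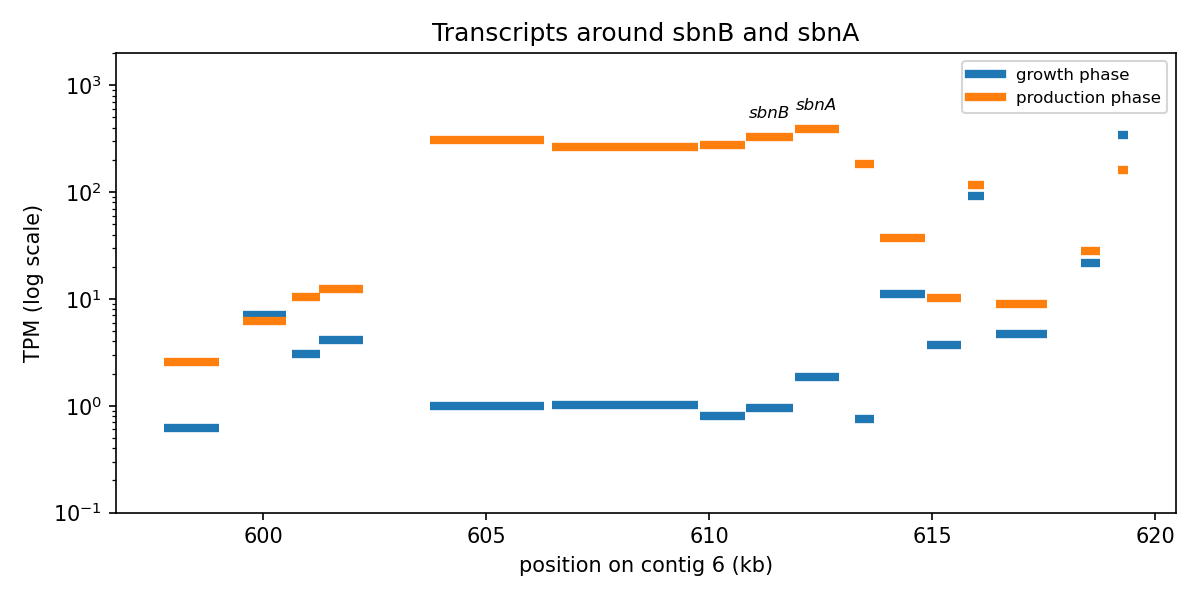
TPM (y axis, log scale) of 16 annotated transcripts around sbnB and sbnA along contig 6 (x axis, kb), each drawn from its start to its end, in the growth-phase library (blue) and the production-phase library (orange). The 6 transcripts from 603725 to 613695 lie at 0.757 to 1.85 TPM in growth and at 181 to 387 TPM in production.

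The other 6 of the 12 highest transcripts had log2 ratios from 5.59 to 5.87. Among them only ctaD carried a symbol. The transcript on contig 6 at 4180807 to 4181301 reached 652 TPM in production from 10.1 in growth, and the transcript at 397011 to 397718 reached 195 TPM from 2.36. Another lay on contig 2 at 301914 to 302885, with 3.45 TPM in growth and 232 in production. None of the 12 lowest transcripts carried a symbol. Their log2 ratios ran from -5.46 to -3.46. The lowest, on contig 6 at 1849941 to 1850105, had 139 TPM in growth and 2.18 in production. The next, on contig 7 at 1013760 to 1015389, had 144 and 6.41 TPM, and the transcript on contig 6 at 2656663 to 2657664 had 57.4 and 2.49 TPM. Also among the 12 was a transcript of 72 nt, shorter than a read equivalent, on contig 6 at 2407671 to 2407742 (189 and 11.7 TPM).

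Among the lists fixed beforehand, 27 had a measured member, 22 had at least 3, and 3 stood apart. No transcript carried a symbol of the polymer synthesis list, so the poly-lysine synthetase gene was not analysed here. The lists of peptide and polyketide synthases, other specialised metabolites and secreted hydrolases likewise had no symbol, and the list of mobile elements had 1 symbol and no measured member.

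The list for the respiratory cytochrome bc-aa3 branch stood apart on the high side, but its measured members were 3 copies of ctaD and coxB, both for cytochrome c oxidase, and none was of the bc complex. These 4 members had a median log2 ratio of 2.08 (1.83 above the overall median), at the 100th percentile of matched random lists and the 99.98th among transcripts with a symbol. The members went together in sign, but the height of the median rested on 2 copies of ctaD, the gene for the catalytic subunit of cytochrome c oxidase. The copy on contig 6 at 976575 to 978266 had 5.62 TPM in growth and 348 in production (log2 ratio 5.72). The copy at 3326144 to 3327817 had 16.9 and 188 TPM (3.40). The most abundant copy, at 3128162 to 3129892 beside coxB and named after its value was seen, had 512 and 798 TPM (0.64), and coxB, for another oxidase subunit, had 601 and 1019 TPM (0.76). In the authors' deposited table these last had log2 fold changes of 0.13 and 0.25. Summed over its 4 copies, ctaD was 2.5-fold higher. With no filter on low values a further ctaD copy entered and the list lay at the 92.0th percentile with a median of 0.76. Both measured members of the cytochrome bd list, for a high-affinity alternative oxidase, were also higher by the size rule. They were cydB, for an oxidase subunit (contig 6, 4953689 to 4954690, 32.5 and 297 TPM, log2 ratio 3.15), and cydD, for a transporter needed in its assembly (4954745 to 4958302, 5.23 and 61.7 TPM, 3.33). The 8 measured members of complex I had a median of 0.36 at percentile 76.9, from -0.74 for a scarce nuoK copy at 4450266 to 4450643 (13.4 and 7.64 TPM) to 0.45 for nuoN. The abundant nuoK copy at 4480057 to 4480356, named after its value was seen, had 125 and 161 TPM (0.37).

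Ribosomal protein transcripts were lower as a group. All 48 measured members had log2 ratios below 0, from -1.41 to -0.16, with a median of -0.91 (-1.16 relative to the overall median). This lay at percentile 0 of the matched random lists and at 0.825 among transcripts with a symbol. The latter background holds these 48 transcripts themselves, so lists drawn from it are partly ribosomal. The lowest were rpsC (-1.41), rplE (-1.40) and rplN (-1.32), and the most abundant, rplJ, had 6638 TPM in growth and 3373 in production (-0.98). No member passed the size rule and 22 were at -1 or below. All of these 22 but rplI lay in 1 region of contig 6, from 4398897 to 4430189. Together these transcripts held 12.8% of TPM in growth and 7.28% in production. Elongation factor genes in the same region of contig 6 had similar values, with -1.42 for fusA and -1.41 for the abundant tuf copy at 4416260 to 4417453. The translation factor list of 11 members, with a median of -0.29 at percentile 19.9, did not stand apart, although all 11 lay below the overall median. Its abundant members were matched on expression to pools not cleared of the ribosomal protein transcripts, which were low themselves.

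Nucleotide biosynthesis transcripts were also lower as a group. The 12 measured members had a median of -0.58 (-0.83 relative to the overall median), at percentile 0.0600 and, among transcripts with a symbol, 0.0400. The lowest were purL (-1.24, from 331 to 140 TPM), carB (-1.11, from 109 to 50.2 TPM) and purS (-1.01, from 583 to 289 TPM). The genes purL and purS encode parts of a step in purine ring synthesis, and carB a subunit of carbamoyl phosphate synthetase, which feeds pyrimidine and arginine synthesis. On contig 6, purL, purQ and purS overlap end to end on the same strand, as do carB and carA. The genes purQ and carA are named after their values were seen. These members may not be independent, as the percentile takes them to be. In 9 of the 12 the ratio was below 0, and the remaining 3, guaB, purU and purD, named after their values were seen, lay at 0.13, 0.06 and 0.04.

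**Figure D3:**
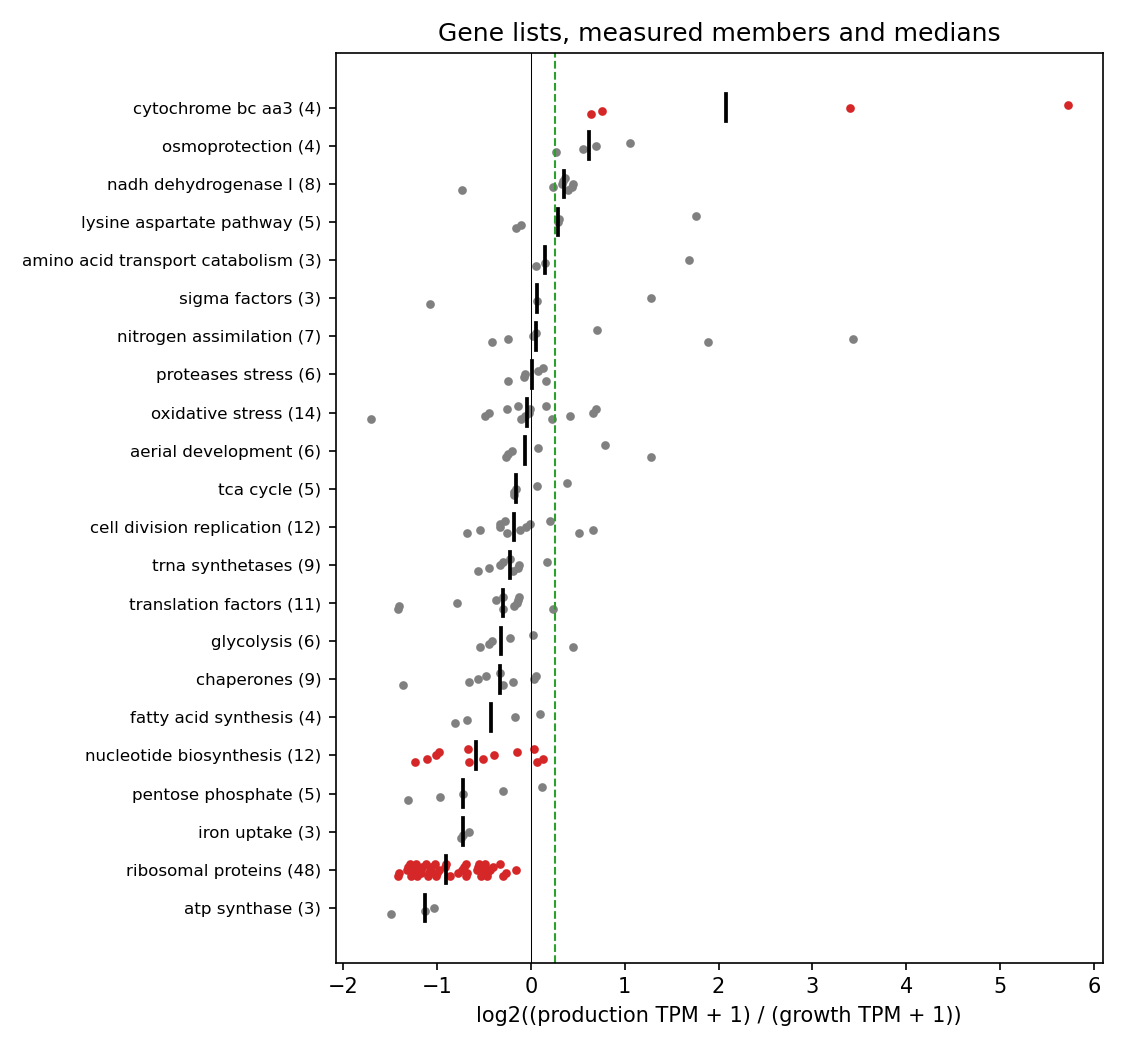
Log2 ratio of production to growth TPM (x axis) of the measured members (points) of the 22 lists with at least 3 measured members, sorted by list median (black bars), with the number of members in parentheses. The dashed green line is the median of all measured transcripts, 0.25, and red points mark the 3 lists past the 1st or 99th percentile, of which ribosomal proteins and nucleotide biosynthesis lie low and cytochrome bc-aa3, here ctaD and coxB, high.

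Measured transcripts with a symbol from the lysine pathway, which supplies the monomer of the polymer, did not stand apart from random lists. They cover only part of the pathway. The dapA gene, named after its value was seen, was not measured (1.24 TPM in growth and 4.02 in production). Steps whose genes carry no symbol were not assessed. The 5 measured members had a median log2 ratio of 0.29 (0.04 above the overall median) at percentile 51.9. The abundant lysA copy, for diaminopimelate decarboxylase, the last step of lysine synthesis, had 113 TPM in growth and 101 in production (contig 7, 845299 to 846690, log2 ratio -0.16). A scarcer lysA copy on contig 6 at 4981477 to 4982811 had 2.56 and 11.0 TPM (1.75), a 4.30-fold ratio with a counting interval of 3.74 to 4.96, and it stayed under the size rule with the pseudocount. The remaining members were dapD (181 and 168 TPM, -0.11) and dapC (73.9 and 90.8 TPM, 0.29), both of intermediate steps, and lysX (190 and 234 TPM, 0.30). The symbol lysX, here on a transcript of 3315 nt, is also used in actinobacteria for an enzyme that joins lysine to tRNA and membrane lipid, so its place in the pathway is uncertain. Without it, a setting added after seeing the data, the list median was 0.09 at percentile 28.2. In the authors' deposited scaling the log2 fold changes of dapC and lysX were -0.22 and -0.21, so no direction is given for them or for the list median. Other small positive values, such as those of ppc and the complex I list, also have a negative sign in that scaling. For anaplerosis, the single measured gene was ppc, for phosphoenolpyruvate carboxylase, at 0.36 (111 and 142 TPM).

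The energy and carbon lists did not stand apart either. The 3 members of ATP synthase, atpD, atpE and atpB, had the values -1.49, -1.13 and -1.04 and a median at percentile 4.24. The pools matched to such abundant transcripts were not cleared of the lower ribosomal protein transcripts. The percentile may therefore understate how low ATP synthase lay. The pentose phosphate list of 5 had a median of -0.72 at percentile 1.33, with tal, for transaldolase, at -1.31 (836 and 337 TPM) and opcA at -0.97. Glycolysis (6 members) had a median of -0.32 at percentile 14.9, and the tricarboxylic acid cycle (5 members) -0.16 at percentile 41.3. Fatty acid synthesis (4 members) had -0.43 at percentile 7.32, and iron uptake and iron-sulfur assembly, represented by sufB, sufC and sufD, had -0.72 at percentile 2.1. The iron list lay below the 1st percentile under 3 other settings, at 0.760 with no filter, 0.950 with FPKM and 0.740 without RNA features. In each of these, bfr (7.77 and 8.26 TPM, 0.08), named after its value was seen, entered as a further member.

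In nitrogen metabolism ureG, for a urease nickel-insertion protein, was higher by the size rule (contig 7, 2998283 to 2998978, 3.84 and 51.3 TPM, log2 ratio 3.43, counting interval of the TPM ratio 11.6 to 15.5). A glnA copy, for glutamine synthetase, on contig 6 at 3233764 to 3235125 had 64.2 and 240 TPM (1.89), while the abundant glnA copy at 3178673 to 3180082 had 905 and 918 TPM (0.02). The list of 7 had a median of 0.05 at percentile 31.4. Among amino acid transport and breakdown genes (3 members, median 0.15, percentile 42.7), gabT, for 4-aminobutyrate aminotransferase, had 31.4 and 104 TPM (1.69). The single measured phosphate gene, phoU, had 0.07.

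Stress, pH and development genes showed values on both sides. The chaperone list of 9 had a median of -0.33 at percentile 14.0, with htpG at -1.36 and dnaK at -0.66. The oxidative stress list of 14 had -0.04 at percentile 19.0, from sodN, for nickel superoxide dismutase (496 and 151 TPM, -1.71), to katG, for catalase-peroxidase (222 and 359 TPM, 0.69). The 6 stress proteases and proteasome genes had 0.01 at percentile 59.5. The only measured pH and cation gene was nhaA, for a sodium/proton antiporter, at 0.93 (23.4 and 45.3 TPM). Osmoprotection, with treS at 1.06, ectA at 0.69 and ectB at 0.56, had a median of 0.62 over 4 members at percentile 89.8. Among 6 development genes (median -0.06, percentile 36.1), whiG, for the sigma factor of spore chain formation, had 6.81 and 18.0 TPM (1.28), and bldC had 1621 and 2814 TPM (0.80). Of 3 sigma factors (median 0.06, percentile 33.9), sigE had -1.07 (465 and 220 TPM). The 9 aminoacyl-tRNA synthetases had -0.22 at percentile 4.93, the 12 replication and division genes -0.18 at percentile 5.87, and rpoB, the only measured RNA polymerase core gene, -0.63 (576 and 373 TPM).

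The authors' deposited table lists 121 of 8383 transcripts at an FDR below 0.05, of which 86 were higher in production and 35 lower, and 7 carried a symbol. The smallest absolute log2 fold change among them was 3.36. All 121 had the same sign of the log2 TPM ratio. Of the 172 and 65 transcripts past the size rule, 67 and 34 were also among them. The authors' deposited log2 fold change was lower than the log2 TPM ratio by a near constant amount, with a median difference of -0.51 over 3599 transcripts with at least 10 TPM in both libraries (5th to 95th percentile -0.54 to -0.47).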

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

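The removal of RNA-type features, the authors' offset alone, the list without lysX, the background of transcripts with a symbol and the joint matching on expression and length were chosen after seeing the data; the other settings were planned. No paired analysis was possible because each phase had 1 library and the result comes from no test.

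The counts were within 1.5 times of 172 higher and 65 lower with a pseudocount of 0.1 TPM (186 and 72), no filter (194 and 66), FPKM (186 and 73), centring on the median or on the trimmed mean (149 and 97 for both), the 10 most abundant transcripts left out (195 and 67) and RNA features left out (190 and 56). They were 84 and 31 with a pseudocount of 10 TPM, which shrinks ratios of low transcripts by construction, and 84 and 43 with a filter of 50 TPM, which leaves 2029 transcripts. Size thresholds of log2 1 and 3 gave 628 and 290, and 96 and 23. The authors' deposited fold changes gave 140 higher and 142 lower, and their offset alone, with the pseudocount kept, gave 129 and 131.

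Centring on the median moves all transcripts alike and cannot move a percentile. Of 219 other list percentiles under alternatives, over 22 lists, 215 kept the call. Only 3 of the 22 lists stood apart, so most kept calls are of lists that did not. The authors' fold changes also shift most transcripts nearly alike, so this count says little about robustness. Cytochrome bc-aa3 dropped to percentile 92.0 without a filter, because a further ctaD copy at 1.55 and 2.40 TPM entered the list. Iron uptake, at percentile 2.1, passed below the 1st percentile with no filter (0.760), with FPKM (0.950) and without RNA features (0.740). In each of these, bfr (log2 ratio 0.08 on the main scale) entered the list. It also entered with the 10 most abundant transcripts left out, where the percentile was 1.29. What share of the shift came from its entry was not tested. Ribosomal proteins stayed at 0 to 0.825 and nucleotide biosynthesis at 0.0300 to 0.190 in every setting run. Of 535 values of 107 named transcripts under alternatives, 0 with a log2 ratio of at least 1 in size changed sign. None of these alternatives could move a ratio of that size past 0, so this outcome was fixed in advance. Smaller values, such as those of dapC and lysX, did change sign. Of the 535 values, 333 moved beyond the counting interval. Depth limits few of these values, since the counting interval is narrow for most measured transcripts; the lack of a second library limits all of them.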

Other observations

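The groupings by shared symbol stem, the counts of neighbouring transcripts, the RNA size classes and the tests of explanations in this part were all chosen after the results were seen.

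Genes with symbols starting in arg, mostly of arginine synthesis, had low values, as a group picked from many after the results were seen. Of 52 groups of at least 3 measured transcripts whose symbols share their first letters, 6 lay past the 1st or 99th percentile of matched random lists. By chance 1.04 such groups would be expected. Among transcripts with a symbol, 3 of the 6 were also past the bounds, while rpl (percentile 1.31) and rps (34.1) were not. That background holds the ribosomal protein transcripts themselves, so it cannot decide whether rpl and rps stand apart. Of the 6, pur, cta, rpl and rps hold members of the lists that stood apart and are no separate result. Only arg and asn were further groups, and of these 2 arg alone was also past the bounds among transcripts with a symbol. The asn group held 3 measured asnB copies, for asparagine synthetase, at 1.56, 1.52 and -0.30, so its copies differed in sign (percentile 99.3, and 98.0 among transcripts with a symbol). The 6 arg transcripts had a median log2 ratio of -0.66 (percentile 0.380), with argH at -1.36, argF at -0.83, argG at -0.70, argJ at -0.63 and argB at -0.59, all of arginine synthesis, and argS, a tRNA synthetase gene, at -0.13. The 3 measured leu genes lay at percentile 98.6, and at 99.8 among transcripts with a symbol, but differed in sign. The abundant pair leuC and leuD on contig 7, for isopropylmalate isomerase, had 486 and 559 TPM in growth and 1203 and 1228 TPM in production (1.31 and 1.13), whereas leuA, for the step before, had 153 and 121 TPM (-0.33). Genes of hopanoid synthesis, which makes sterol-like membrane lipids, had positive values, with shc, for squalene-hopene cyclase, at 1.27, hpnH at 1.26, hpnC at 1.20 and hpnD at 0.41. The 3 hpn genes lay at percentile 98.0, within the outer bounds, so they did not stand apart. Of single genes, hisC on contig 6, for an aminotransferase of histidine synthesis, had the lowest ratio of all measured transcripts with a symbol (-1.72, 85.2 and 25.1 TPM).

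Short RNA features had lower TPM in production. Of 70 RNA-type features without a symbol and 71 to 91 nt long, 51 were measured. Their median log2 ratio was -1.04, 45 were below 0 and 10 were at -2 or below. Their summed abundance was 12304 TPM in growth and 4803 in production. These features are shorter than the 100-base unit of the read equivalents. How well the libraries captured such short RNAs was not tested, so a change in the mature RNAs is not shown. The 7 features of 1529 nt had a median of -1.41 and the 7 of 3120 to 3122 nt one of -0.93, in libraries from which ribosomal RNA had been depleted. The 4 members of the ribosomal protein list that stayed below 10 TPM, all on contig 6, had positive ratios, with rpmF (5103552 to 5103722) at 1.77, rpsN at 1.18, rpmB at 0.53 and rpmG (5288873 to 5289037) at 0.31. Scarce transcripts in general had positive ratios too.

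Transcripts past the size rule followed each other in the order of measured transcripts more often than shuffled positions give. Unmeasured transcripts between them were skipped, so the members of a run need not be adjacent on the contig. Of the 172 higher transcripts, 79 (45.9%) stood in 14 runs of at least 3 neighbours among measured transcripts, and 1000 shuffles gave a mean of 0.770 and at most 9. Of the 65 lower ones, 28 (43.1%) stood in 6 runs, against at most 4. Both the runs and the shuffles used only measured transcripts. A transcript at 1 TPM or less in growth is measured only if it reaches 10 TPM in production, which already passes the size rule. The reverse holds for the lower direction. The filter thus partly sets the runs, so the shuffles do not decide on random placement along the contigs. Co-transcribed gene clusters are a candidate explanation for the 8 higher and 6 lower runs that lie on 1 strand. The other 6 higher runs, among them the 3 longest, hold transcripts of both strands and cannot each be a single transcription unit. The longest higher runs held 18 transcripts on contig 2 (1089 to 95354), 12 on contig 6 (394210 to 407019) and 9 on contig 7 (3282660 to 3290552), all without a symbol. On contig 2, 22 of 118 measured transcripts (18.6%) were higher, compared with 8.64% on contig 1, 3.51% on contig 6 and 3.32% on contig 7. Over all annotated transcripts, measured or not, the shares were 6.83% on contig 2, 2.44% on contig 1, 1.91% on contig 6 and 1.78% on contig 7. The longest lower runs held 7 transcripts on contig 7 from 2740606 to 2749618 and 6 from 3095059 to 3100986. Other lower runs held 5 transcripts within 2407389 to 2407853 on contig 6 and 3 within 1153336 to 1153590 on contig 7. Transcripts this closely packed are about the size of the short RNA features, whose capture was not tested.

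The lower values of ribosomal protein transcripts were set against technical explanations. A single scale difference between the libraries, such as a few transcripts taking most of the signal, moves all transcripts alike, but the list lay -1.16 from the overall median (bootstrap interval -1.33 to -0.94). Short length and high level as the whole cause were also argued against, since the list lay -0.72 (-1.04 to -0.39) from 33 other coding transcripts in its 10th to 90th percentile range of length and level. Those 33 transcripts were themselves at -0.44 (-0.63 to -0.13) relative to the overall median, so length or level may account for part of the difference. Ribosomal protein genes without a symbol were not excluded from the 33, so their low median need not come from length or level. The bootstrap intervals treat transcripts as independent. Many of the ribosomal protein transcripts are close neighbours on the same strand and may be transcribed together. The intervals may therefore be too narrow, which weakens the argument against length and level as the whole cause. How wide they would be with neighbours resampled together was not tested. The change from growth to production phase stays open and untested, since each phase had 1 library.

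Reads shared between copies could make a copied gene look higher at the cost of its other copies, while the sum over copies stays as it was. The genes sbnB, sbnA, cydB, corA and ccrA had 1 copy each past the size rule. TPM summed over all copies with the same symbol was at least 4-fold higher in 5 of 5. The sums ran from 4.24-fold for ccrA to 233-fold for sbnB, which argues against reads moved from copies with the same symbol. Most transcripts carry no symbol, so copies among those could not be summed and reads moved from them were not assessed. For ctaD, with 2 copies past the size rule, the sum was 2.5-fold higher (536 and 1337 TPM). No other ctaD copy was lower, and for the 514 TPM gained to have come from the abundant copy, that copy would need a true 2.56-fold increase, against 1.69-fold for coxB beside it and 1.56-fold as measured. Whether coxB tracks the abundant copy was not tested, so moved reads stay open for ctaD, as does the phase of the culture for all of these genes.

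Transcripts scarce in growth had higher TPM in production almost throughout. Of 3289 transcripts of at least 300 nt with less than 5 TPM in growth, 5.32% had no increase, and the median increase was 1.77 TPM (quartiles 0.978 and 2.65). A candidate explanation is a uniform background of reads in the production library, from DNA or unspecific transcription. Such a background would leave few transcripts under its own level, and 4.96% of 7623 transcripts had an upper counting limit under 1.77 TPM, where counting error alone allows 2.5%. Uneven coverage of a background by base composition was not computed without a genome sequence, so background and a true broad increase cannot be told apart for these scarce transcripts.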
